A study of Arabidopsis thaliana with 16 samples.

How the data were processed

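Whole seedlings of the wild type Col-0 and of ABI3:GR were grown on MS agar with a selective antibiotic and treated at 2 weeks for 4 h with mock solution, ABA, DEX or both, per the labels' protocols. Total RNA was extracted with an RNeasy kit and 100 ng was labelled with Cy3 for one-colour Agilent 44k arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which gave 8 groups of 2 arrays. The files used were the 16 scanner outputs and the table of processed values. Per the file headers, the processed signal is an intensity on a linear scale that Feature Extraction had spatially detrended, background-subtracted and multiplicatively detrended, with a surrogate value for spots at background. The Feature Extraction version is 9.5.3.1 per the file headers and 10.7.3.1 per the submitters' processing notes. The deposited value table holds linear intensity for 41612 probes, with a median of 248.2 in every column and a correlation of 0.999 to 1.00 (log2) with the scanner signal of the same array; 1991 of the probes on the arrays are not in it. All its columns have the same distribution, which points to quantile normalization, a step that no source used here names.

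Each array has 45220 spots, of which 1417 are controls and were left out. The others hold 43603 probes, and replicate spots of a probe were averaged after leaving out spots marked as outliers, 3 to 15 per array. Saturated spots, 3 on 1 array (ABI3:GR mock replicate 1) and 0 on the others, were kept. Probe names follow the loci in the files: 39057 probes have a locus and 4546 do not, 876 list several loci, and 28608 of 29043 loci matched the RefSeq gene table, from which symbols were taken; the other 435 kept the name in the file. Several probes read 7744 of the loci, and a gene was represented by the probe with the highest mean over the 16 arrays. Of 99 called values of named genes that have another tested probe, 82 had every other probe called the same way and 3 had another probe of opposite sign; the probe of 1 named gene, BZIP53, lists several loci.

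Signals were taken to log2 and each array's 75th percentile was subtracted. A probe was tested if it was well above background, as Feature Extraction marks it, on both arrays of at least 1 group, which left 21835 genes, 19510 of them above background on all arrays. One limma model (lmFit and eBayes, version 3.58.1, in R 4.3.3 with version 1.17.8 of data.table and statmod 1.5.0) with a mean per group was fitted to the 16 arrays, with 8 residual degrees of freedom and a prior of 2.02. The 13 comparisons were contrasts of this model, with Benjamini-Hochberg adjustment within each, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Where a group was not above background on either array, a fold is a bound, computed on the means of the normalized log2 values against the lowest well-above-background signal of each array, or the probe's own if higher. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

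Fixed lists, 19 with 290 genes in all, cover seed storage and oil body proteins, LEA and desiccation proteins, maturation regulators, seed oil synthesis, raffinose sugars, ABA and drought markers, ABA-linked PP2C phosphatases, ABA receptors, ABA synthesis and breakdown, light harvesting, expansins, early auxin, type-A response regulators, mitosis, heat shock, jasmonate, low oxygen, root markers and salicylate defence. Camera was run with a preset correlation of 0.01 on the 18 lists with at least 5 tested members, adjusted over lists within a comparison. Of the 234 pairs of list and comparison, 78 had an adjusted p under 0.05, and 14 of these kept it with an estimated correlation: 4 for ABA in wild type, 3 for ABA plus DEX in wild type, 4 for ABA in ABI3:GR and 3 for ABA plus DEX in ABI3:GR. With the replicate number as a block 2 of the 14 lost it, jasmonate for ABA in wild type (0.108) and receptors for ABA in ABI3:GR (0.119, and 0.106 without wild type DEX replicate 2). With the slide as a block 7 lost it, markers and PP2C for ABA plus DEX in wild type (0.0600 each) and in ABI3:GR (0.0573 each), and markers, PP2C and receptors for ABA in ABI3:GR (0.0500, 0.0530 and 0.0500), and receptors for ABA in wild type gained it (0.0414). The named genes are ABI3 and 16 fixed seed and ABA genes, the 6 largest rises and 4 largest falls among called genes of the main comparisons (3 each way in the others), and from each list with a called member up to 4 called members and 2 that were not called; those chosen after their values were seen are marked where they stand. These lists, this rule and the alternatives were fixed before the data were examined, except that leaving wild type DEX replicate 2 out of every model was added after seeing the data.

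The scanner files place the arrays on 4 slides read on 2 scan days, each slide holding the 4 treatments of 1 genotype and 1 replicate number. The replicate number is the biological experiment, per the series design, and a scan day, so it pairs arrays. Deviations of same-numbered arrays from their group means correlated between 0.0982 and 0.585 over the 28 pairs of groups (0.152 to 0.300 within wild type, 0.285 to 0.585 within ABI3:GR, 0.0982 to 0.388 between genotypes), but the reported model has no block. A fit with the number as a block is an alternative, given beside a result where it changes a call or moves a count over 1.5 times. The alternatives were quantile normalization, normexp (offset 50) on mean and background signals, the value table, no filter, only probes above background on all arrays, the replicate number as a block (the replicate block), the slide as a block (the slide block, random between genotypes), no minimum fold, only the arrays of a comparison, eBayes with trend and robust, the mean of all probes of a gene, and each array left out in turn.

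The model was tested on 21811 simulated genes, with changes of log2 size 1, 2 or 4 in 67, 67 and 66. It called 29.9, 77.6 and 98.5% of them for ABA in wild type and 25.4, 61.2 and 83.3% for genotype by ABA. None went the wrong way, and 1 to 7 unchanged genes were called. Each time camera found only the 1 shifted list, but correlation within lists was not tested.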

Results

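RNA of whole Arabidopsis thaliana seedlings, 2 weeks old, was measured on 16 one-colour arrays. The wild type was Col-0. The other genotype, ABI3:GR, carried a 35S promoter construct in which ABI3, a transcription factor that acts in seed maturation and in abscisic acid (ABA) signalling, is fused to the glucocorticoid receptor. Such fusions are in general kept inactive until a glucocorticoid such as dexamethasone (DEX) binds the receptor part. Each genotype was given mock solution, ABA at 10 µM, DEX at 30 µM, or both, for 4 h, with 2 arrays per group in 8 groups. A group's arrays came from 2 independent biological experiments, per the series design, and p-values pool their spread over the 8 correlated groups. Between 68.0 and 75.3% of the spots of an array were well above background, and the median processed signal of an array ran from 121 to 260. Precision is limited by the number of arrays. The 2 arrays of a group correlated between 0.982 (ABI3:GR, mock) and 0.995 (wild type, ABA) across genes. In wild type with DEX, 41 genes differed by more than 4 (log2) between the arrays, against 4 to 18 genes in the other groups. Of these 41, 40 were higher on replicate 2 and 21 belonged to the storage protein or late embryogenesis abundant (LEA) lists.

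ABI3 (AT3G24650) RNA was far more abundant in ABI3:GR than in wild type. Its log2 level was 2.31 to 3.55 on the 8 ABI3:GR arrays and -9.13 to -5.74 on the 8 wild-type arrays. Of the latter, mock replicate 1 and DEX replicate 2 were above background. Under mock treatment the difference was 10.49 ± 0.85 (log2 ± SE, limma, adjusted p = 0.000413, n = 2 arrays per group). Neither ABA (-0.43 ± 0.85, adjusted p = 0.716) nor DEX (0.09 ± 0.85, adjusted p = 0.986) gave a call for ABI3 within ABI3:GR. The SE pools wild-type arrays at background, so stable RNA is not shown. All arrays with ABA (2.31 to 2.88), but none with DEX alone, lay below the mock arrays (2.93 and 3.55). With the 4 mock arrays alone the adjusted p of the genotype difference was 0.0618.

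**Figure D1:**
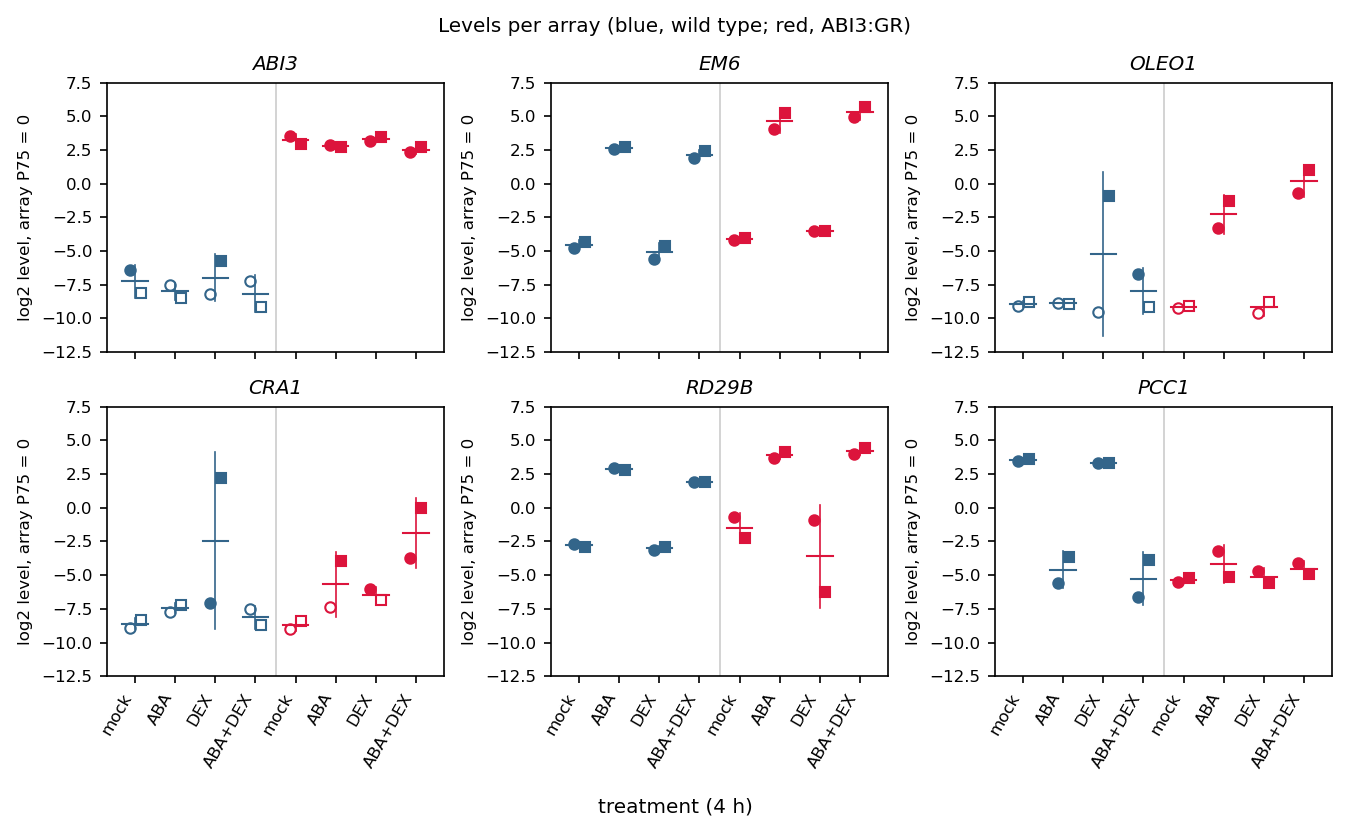
Log2 level of ABI3, EM6, OLEO1, CRA1, RD29B and PCC1 on each array (vertical axis, log2 processed signal minus the array's 75th percentile) in the 8 groups (horizontal axis, wild type in blue, ABI3:GR in red); circles are replicate 1, squares replicate 2, open symbols are arrays where the probe was not well above background, bars are means and lines the SD (n = 2). ABI3 lies between 2.31 and 3.55 on the ABI3:GR arrays and at -5.74 or lower on the wild-type arrays.

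ABA changed a large part of the wild-type transcriptome, with RNAs of seed desiccation proteins among those that rose. AT3G17520, a LEA family gene, rose at least 3744-fold (adjusted p = 0.000111) and TSPO, a membrane protein gene, at least 2519-fold (adjusted p = 7.08e-07). A bound of this kind compares the brighter group's mean with the lowest well-above-background signal on the dimmer group's arrays. It is given between 2 groups wherever the dimmer was not above background on either array. With only 1 array of the brighter group above background it is not strict. LEA7 rose by 11.93 ± 1.43 (log2 ± SE, adjusted p = 9.48e-05). Falls included the ABA receptor gene PYL6, at least 236-fold (adjusted p = 9.16e-08), and 3 genes that respond to pathogens or salicylate, PCC1 (-8.14 ± 0.92, adjusted p = 6.32e-05), LURP1 (-8.14 ± 0.93, adjusted p = 6.84e-05) and ANK (-8.13 ± 0.71, adjusted p = 1.18e-05).

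Of the LEA and desiccation list, 18 of 22 tested members rose in ABA-treated wild type and none fell, with a median log2 change of 6.50 (4.68 with members below background at their bound). EM6 (AT2G40170) rose by 7.21 ± 0.42 (adjusted p = 8.62e-07), EM1 (AT3G51810) at least 122-fold (adjusted p = 2.98e-05) and LEA4-5 at least 567-fold (adjusted p = 2.05e-06). RAB28 stood at 1.98 ± 0.74 (adjusted p = 0.0546). In camera the list lay higher than other genes (adjusted p = 4.78e-10, and adjusted p = 0.209 with an estimated correlation, 19 called when adjusted over the list alone). The seed storage and oil body list had 2 rises among 20 members in wild type. Its median was 0.56 (0.00 with bounds), and the camera test gave adjusted p = 0.133, with 1 when adjusted over the list alone. AT2G18540, a cupin family storage gene, rose at least 20.6-fold (adjusted p = 0.000130). The 2S albumin genes SESA1 and SESA3, the cruciferin genes CRA1 and CRC and the oleosin genes OLEO1 and OLEO2 were not well above background on any mock or ABA array of wild type. The other rise of this list, AT4G36700 (3.63 ± 1.26, adjusted p = 0.0400), was not called without any single array of the 4 (adjusted p 0.115 to 0.130), nor with the slide block (0.0564) or no filter (0.0602).

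The ABA signalling lists moved strongly. All 9 tested PP2C phosphatase genes, negative regulators of ABA signalling, rose with a median of 4.69 (4.50 with bounds; camera adjusted p = 6.02e-11, and adjusted p = 0.0148 with an estimated correlation). HAI1 (AT5G59220) rose by 8.94 ± 0.48 (adjusted p = 5.70e-07) and ABI1 (AT4G26080) by 3.47 ± 0.13 (adjusted p = 9.16e-08). Of 27 ABA and drought markers, 26 rose, with a median of 4.60 (adjusted p = 2.46e-22, and adjusted p = 0.0123 with an estimated correlation). RD29B (AT5G52300) rose by 5.64 ± 1.26 (adjusted p = 0.00474) and RAB18 (AT5G66400) by 2.31 ± 0.47 (adjusted p = 0.00285). Of 9 ABA receptor genes, 7 fell, among them PYL4 (-6.10 ± 0.25, adjusted p = 1.35e-07), and the list median was -1.83 (adjusted p = 0.000389, and adjusted p = 0.0512 with an estimated correlation). Of 13 genes of ABA synthesis and breakdown, 9 rose with a median of 2.09 (1.73 with bounds; adjusted p = 2.06e-07, and adjusted p = 0.0123 with an estimated correlation). They included NCED3, which makes the ABA precursor (5.53 ± 0.38, adjusted p = 2.38e-06), and CYP707A1, which breaks ABA down (4.85 ± 0.29, adjusted p = 9.76e-07). Adjusted over the list alone, the counts of called members were 9 for PP2C, 26 for markers, 7 for receptors and 9 for synthesis and breakdown.

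Few maturation regulators were called with ABA in wild type. ABI5 (AT2G36270), a bZIP factor of ABA signalling, rose by 3.63 ± 0.38 (adjusted p = 4.02e-05) and DOG1, a dormancy gene, by 2.21 ± 0.39 (adjusted p = 0.00122), the 2 rises among 14 tested maturation regulators (adjusted p = 0.290; 2 when adjusted over the list alone). LEC1 (AT1G21970) stood at -0.31 ± 0.50 (adjusted p = 0.669). FUS3 and LEC2 were above background on at most 1 array of each group and were not tested. SUS3, a sucrose synthase, was the 1 rise among 15 seed oil synthesis genes (4.19 ± 0.25, adjusted p = 9.48e-07; list median -0.04 with an upward camera test, adjusted p = 0.257; 1 when adjusted over the list alone). Of 7 genes of raffinose sugars, 4 rose (adjusted p = 0.0142, and adjusted p = 0.197 with an estimated correlation; 5 when adjusted over the list alone), with the galactinol synthase GOLS2 at 6.95 ± 0.37 (adjusted p = 5.54e-07).

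Among lists not tied to seeds, 10 of 21 jasmonate and wounding genes rose and none fell (adjusted p = 5.29e-07, and adjusted p = 0.0486 with an estimated correlation, 0.108 when the replicate number was also a block; 10 when adjusted over the list alone), with VSP2 at 4.68 ± 0.34 and JAZ7 at 3.58 ± 0.38 (adjusted p = 3.83e-06 and 4.39e-05). Of 10 expansins, which loosen cell walls, 5 fell (adjusted p = 0.0211, and adjusted p = 0.412 with an estimated correlation; 5 when adjusted over the list alone), EXPA8 by at least 58.2-fold (adjusted p = 1.50e-06). With the probes above background on all arrays the expansin list had adjusted p = 0.0507. Of 13 root markers, 6 fell (adjusted p = 0.0308, and adjusted p = 0.522 with an estimated correlation; 9 when adjusted over the list alone). The nitrate transporter NRT2:1 fell at least 6.22-fold (adjusted p = 0.00131). The list call was lost without wild type ABA replicate 2 (adjusted p = 0.0648), with normexp (0.0991), with probes above background on all arrays (0.0633) and with the mean of all probes (0.0670).

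Other lists did not pass in ABA-treated wild type. Of 17 heat shock genes 3 rose and 1 fell (camera adjusted p = 0.207; 4 when adjusted over the list alone), with HSP22 up at least 25.3-fold (adjusted p = 1.54e-06). Of 15 low oxygen genes 3 rose and 4 fell (adjusted p = 0.860; 7 when adjusted over the list alone). ADH1 rose by 3.46 ± 0.16 (adjusted p = 2.38e-07) while HB1 fell by 2.71 ± 0.40 (adjusted p = 0.000408). Of 14 early auxin genes 2 rose and 3 fell (adjusted p = 0.534; 5 when adjusted over the list alone). Of 8 type-A cytokinin response regulators 3 fell (adjusted p = 0.329; 3 when adjusted over the list alone), and ARR7 fell by 1.79 ± 0.35 (adjusted p = 0.00211). None of 22 light harvesting and Rubisco genes (median 0.02, adjusted p = 0.496) and none of 10 mitotic genes (median -0.06, adjusted p = 0.860) was called by limma, over all genes or adjusted over the list alone, with 1 and 2 members at unadjusted p under 0.05. The salicylate defence list had 2 tested members (of PR1, PR2 and PR5), none called and 1 at unadjusted p under 0.05, at a median of -0.31, too few for a list test.

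In all, limma called 1999 genes higher and 2247 lower in ABA-treated wild type among 21835 tested. Across the genes tested the median change was -0.12 here, -0.12 for ABA in ABI3:GR and -0.15 for ABA plus DEX in ABI3:GR. More were called higher than lower after quantile normalization (2083 and 2040), in the value table (2062 and 2008) and with normexp (1543 and 1328). With no minimum fold the ABA count was 9487.

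In ABI3:GR, ABA raised storage and oil body RNAs along with the LEA group. OLEO2 (AT5G40420), an oil body coat protein, rose at least 64.4-fold (adjusted p = 0.00294), TIP3;1, a seed vacuole membrane channel, by 6.59 ± 1.42 (adjusted p = 0.00372) and AT2G18540 by 7.07 ± 0.62 (adjusted p = 1.28e-05). EM1 rose at least 1292-fold (adjusted p = 8.42e-06), EM6 by 8.71 ± 0.42 (adjusted p = 2.81e-07), AT2G42560, another LEA gene, at least 433-fold (adjusted p = 2.45e-07), AT3G17520 by 11.63 ± 1.67 (adjusted p = 0.000309) and LEA7 by 11.52 ± 1.43 (adjusted p = 0.000118). Falls included CRK30, a receptor-like kinase, at least 198-fold (adjusted p = 1.19e-07) and PYL6 (-8.45 ± 0.31, adjusted p = 8.33e-08).

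Of the storage and oil body list 11 of 20 members rose in ABI3:GR with ABA, at a median of 4.35 (3.46 with bounds; adjusted p = 0.000377, and adjusted p = 0.536 with an estimated correlation; 11 when adjusted over the list alone). The median was 2.60 in experiment 1 and 5.60 in experiment 2. OLEO1 (AT4G25140) rose at least 26.0-fold (adjusted p = 0.0217). It lost the call without either ABI3:GR mock array or ABA replicate 2 (0.0687 to 0.114) and with normexp (0.0507). CRC (at least 11.2-fold higher, adjusted p = 0.182), CRA1 (2.44-fold, 0.342) and SESA1 (1.05-fold, 0.520) were not called. Nor was SESA3 (0.996), not well above background in either group. CRA1 and SESA1 were above background on 1 of the 2 ABA arrays, so theirs are no strict bounds. Of the LEA list 21 of 22 members rose, at a median of 8.63 (8.05 with bounds; adjusted p = 5.41e-13, and adjusted p = 0.181 with an estimated correlation; 21 when adjusted over the list alone). In all 2074 genes were called higher and 2166 lower by limma, a balance that turned with normexp (1711 and 1212), the 4 arrays alone (1766 and 1713) and without mock replicate 1 (2256 and 1994) or ABA replicate 2 (2074 and 1915).

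With ABA and DEX together, LEA and oleosin RNAs rose strongly in ABI3:GR. AT4G36600, a LEA family gene, rose at least 3392-fold (adjusted p = 3.28e-06), AT2G25890, an oleosin family gene, at least 1766-fold (adjusted p = 2.66e-05) and EM1 at least 3858-fold (adjusted p = 4.46e-06). Of 20 storage and oil body genes 18 rose, at a median of 6.94 (5.83 with bounds; adjusted p = 2.99e-08, and adjusted p = 0.350 with an estimated correlation; 18 when adjusted over the list alone). OLEO1 rose at least 140-fold (adjusted p = 0.00497), OLEO2 at least 191-fold (adjusted p = 0.000811) and TIP3;1 by 9.58 ± 1.42 (adjusted p = 0.000419). Of 22 LEA genes 21 rose, at a median of 9.89 (9.13 with bounds; adjusted p = 4.06e-16, and adjusted p = 0.118 with an estimated correlation; 21 when adjusted over the list alone). ABI5 rose by 5.42 ± 0.38 (adjusted p = 3.97e-06), EM6 by 9.39 ± 0.42 (adjusted p = 2.84e-07) and AHG1, a seed PP2C, at least 129-fold (adjusted p = 1.83e-06).

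Under both treatments cruciferin and 2S albumin calls were unstable. CRC (AT4G28520) rose at least 151-fold (adjusted p = 0.0275), SESA1 (AT4G27140) at least 31.5-fold (adjusted p = 0.0285) and CRA1 (AT5G44120) at least 34.0-fold (adjusted p = 0.0412). SESA3 (AT4G27160), at least 10.5-fold higher, was not called (0.195). The tests also pool the wide spread of wild type DEX, in neither group. CRC and SESA1 lost the call without any single array of the 4. CRA1 lost it without either mock array or ABA plus DEX replicate 2 (0.0939 to 0.225), with normexp (0.175), quantile normalization (0.0539), the value table (0.0517), no filter (0.0613) and the mean of its probes (0.117). In all 1884 genes were called higher and 2201 lower, but 1495 and 1346 with normexp and 2041 and 1917 without mock replicate 1.

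The double treatment of wild type serves as the control. Of 20 storage and oil body genes 1 rose there, at a median of 0.67 (0.00 with bounds; adjusted p = 0.242; 1 when adjusted over the list alone). Of 22 LEA genes 16 rose, at a median of 5.85 (3.90 with bounds; adjusted p = 3.97e-08, and adjusted p = 0.291 with an estimated correlation; 17 when adjusted over the list alone). EM6 rose by 6.69 ± 0.42 (adjusted p = 1.89e-06), EM1 at least 37.0-fold (adjusted p = 0.000147) and ABI5 by 3.13 ± 0.38 (adjusted p = 0.000125). In all 1885 genes were called higher and 1977 lower. The balance turned after quantile normalization (1965 and 1881), in the value table (1943 and 1854), with normexp (1416 and 1178), with probes above background on all arrays (1577 and 1504) and without mock replicate 1 (1786 and 1751) or ABA plus DEX replicate 1 (1746 and 1673). The expansin list (adjusted p = 0.0491, and adjusted p = 0.575 with an estimated correlation) was not called with the replicate block (0.0683), with the slide block, quantile normalization, the value table, probes above background on all arrays, the mean of all probes or only the arrays of the comparison, or without wild type ABA plus DEX replicate 1 (0.0541 to 0.0961).

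**Figure D2:**
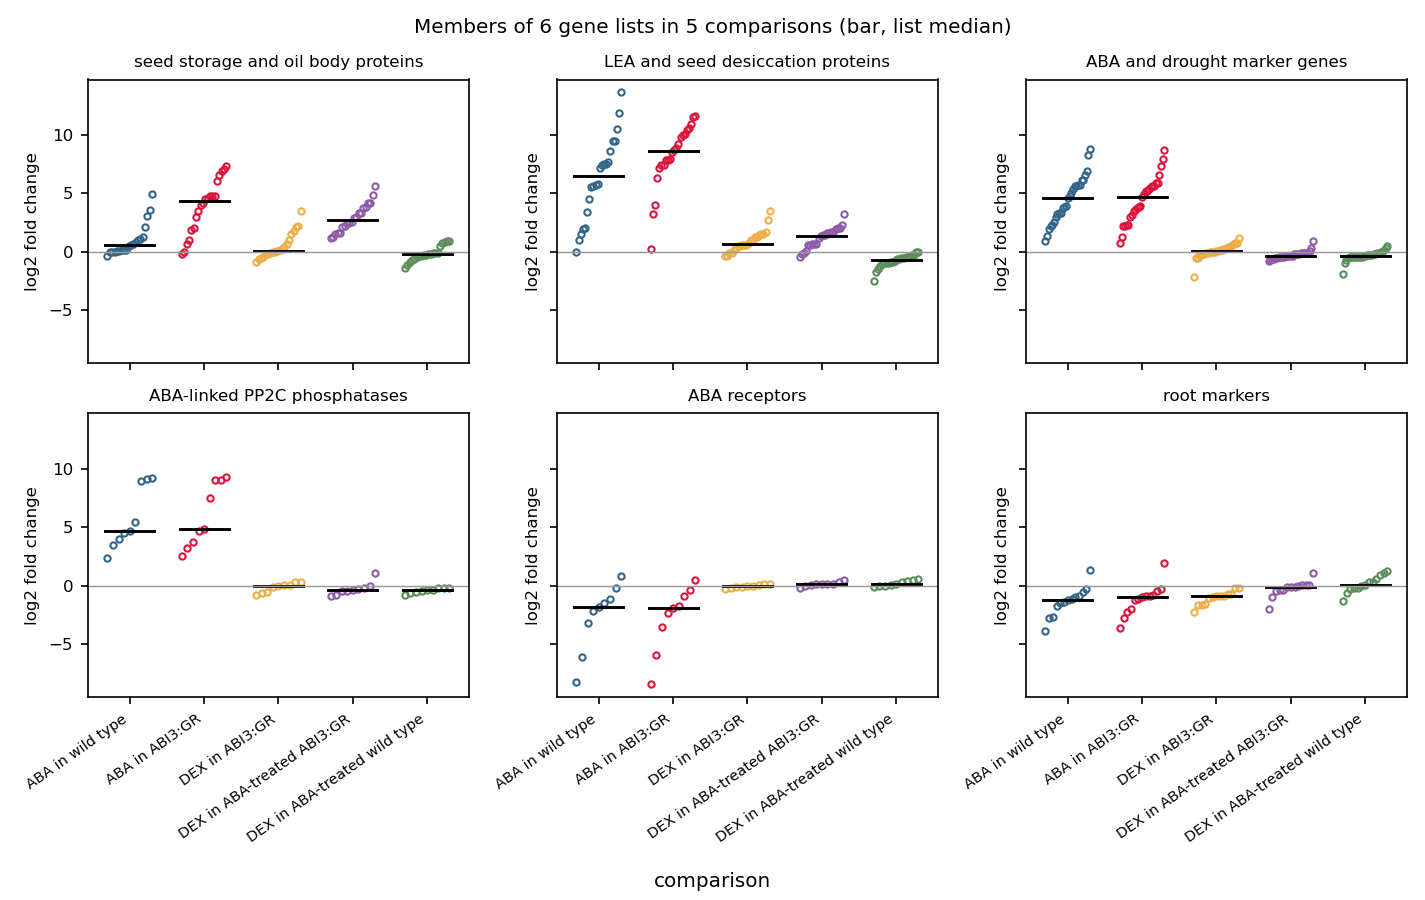
Log2 fold change (vertical axis) of each tested member (points) of 6 gene lists (panels) in 5 comparisons (horizontal axis), with the list median as a bar and members in order of their value. The storage and oil body list has a median of 0.56 for ABA in wild type and 4.35 for ABA in ABI3:GR (0.00 and 3.46 with bounds).

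Under mock treatment more genes were called lower than higher in ABI3:GR. ANK, an ankyrin repeat gene, was at least 303-fold lower (adjusted p = 0.000413), and PCC1 (-8.89 ± 0.92, adjusted p = 0.00172) and AT5G03350, a lectin family gene (-6.79 ± 0.43, adjusted p = 0.000217), were lower as well. Beside ABI3 itself, QQS, a gene that affects leaf starch (3.13 ± 0.46, adjusted p = 0.0123), and AT5G42510, at least 2.65-fold (adjusted p = 0.0127), were higher. QQS lost its call without wild type mock replicate 2 (adjusted p = 0.116) or ABI3:GR mock replicate 1 (0.0995), and AT5G42510 without wild type mock replicate 1 (0.0961) or ABI3:GR mock replicate 1 (0.104) and with normexp (log2 0.44, adjusted p = 0.740). In all 19 genes were called higher and 91 lower by limma (5 and 74 with normexp). The count of calls was 53 without wild type mock replicate 1 and 71 (5 higher, 66 lower) without wild type mock replicate 2, and 4 with only the mock arrays in the model.

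Named seed genes gave no call between the mock-treated genotypes. EM6 stood at 0.45 ± 0.42 (adjusted p = 0.968). OLEO1, OLEO2, CRA1, CRC, SESA1, SESA3 and EM1 were not well above background in either group. The medians of the storage list (0.04, camera adjusted p = 0.986) and the LEA list (0.50, 0.232) rest on levels at background and are both 0.00 with bounds. Root markers (median 0.85, adjusted p = 2.40e-05), low oxygen genes (0.58, 2.01e-08), early auxin genes (0.26, 0.000287) and jasmonate genes (0.15, 0.0199) lay higher in ABI3:GR and mitotic genes lower (-0.28, 0.000121), each with adjusted p = 0.371 to 0.430 with an estimated correlation. No member of these 5 lists was called by limma over all genes, with 6, 7, 4, 4 and 2 at unadjusted p under 0.05. Adjusted over the list alone the counts were 2, 2, 0, 0 and 0. The auxin call was lost without ABI3:GR mock replicate 2 (adjusted p = 0.479). The jasmonate call was lost without wild type mock replicate 1 (0.321), without ABI3:GR mock replicate 2 (0.259) and with the mean of all probes (0.0618).

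DEX alone changed few genes in wild type, the comparison the design includes as a control for DEX itself. AT3G13310, a DnaJ domain gene chosen after its values were seen, rose by 2.19 ± 0.22 (adjusted p = 0.0166). AT2G44130 rose by 3.47 ± 0.41 (adjusted p = 0.0265), AOP3, an enzyme gene of glucosinolate side chains, at least 1.76-fold (adjusted p = 0.0166) and ATGLR1.2, a glutamate receptor-like gene, at least 1.47-fold (adjusted p = 0.0166). AT3G30817 fell at least 4.00-fold (adjusted p = 0.0265). These are all of the calls, 4 higher and 1 lower (4 and 0 after quantile normalization, 3 and 0 with normexp). The replicate block gave 12 calls and the slide block 9. The arrays of the comparison alone gave 0 in limma, where the 16-array model had 1305 genes at unadjusted p under 0.05. The count was 0 without wild type mock replicate 1, 11 (7 higher, 4 lower) without wild type DEX replicate 2, 12 (3 higher, 9 lower) without wild type mock replicate 2 and 18 (18 higher, 0 lower) without wild type DEX replicate 1. AT2G44130 lost its call without either wild type mock array or DEX replicate 1 (adjusted p 0.0705 to 0.154), AOP3 without mock replicate 1 (0.124) and ATGLR1.2 without mock replicate 1 or DEX replicate 2 (0.125 and 0.0673). AT3G30817 lost it without mock replicate 1 or either DEX array (0.0678 to 0.163) and with the slide block (0.0665). AOP3, ATGLR1.2 and AT3G30817 also lost it with normexp (log2 0.21, 0.0043 and -1.11), with quantile normalization (adjusted p = 0.0553, 0.0627 and 0.0553) and with trend and robust (0.0746, 0.0746 and 0.0936). So did ATGLR1.2 in the deposited value table (0.0529), and AT2G44130 and AT3G30817 with no filter (0.0524 each).

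The storage and oil body list had a median of 3.22 in DEX-treated wild type (1.71 with bounds), which split into 0.17 in experiment 1 and 6.67 in experiment 2. Camera gave adjusted p = 2.94e-10, and adjusted p = 0.627 with an estimated correlation, and adjusted p = 0.617 without wild type DEX replicate 2. No member was called by limma, over all genes or adjusted over the list alone, with 4 at unadjusted p under 0.05. Of its 20 members 4 were well above background in both groups and the others have only bounds. CRA1 was at least 20.3-fold higher (adjusted p = 0.803). CRC was 11.3-fold higher (adjusted p = 0.835), not a strict bound, being well above background on DEX replicate 2 alone (log2 level 2.51). The LEA list (median 1.41, 0.51 with bounds; adjusted p = 0.000278, and adjusted p = 0.741 with an estimated correlation) had a median of -0.24 and adjusted p = 0.732 without the same array, and adjusted p = 0.546 with probes above background on all arrays (0 when adjusted over the list alone in limma, 3 at unadjusted p under 0.05). ABA markers (0.13, adjusted p = 0.000278), early auxin genes (0.29, 0.00447) and expansins (0.23, 0.0358) lay slightly higher, each with adjusted p = 0.627 to 0.741 with an estimated correlation. These lists had 1, 0 and 0 members called when adjusted over the list alone and 5, 1 and 3 at unadjusted p under 0.05. The auxin call was lost without wild type DEX replicate 1 (adjusted p = 0.0590). The expansin call was lost without mock replicate 1 or DEX replicate 1 (0.127 and 0.293), with the replicate block (0.0615), with the slide block (0.0965) and with only the arrays of the comparison (0.0712). Heat shock genes (median -0.29, adjusted p = 0.107) lay at -0.62 and passed without wild type DEX replicate 2 (5.64e-05, and adjusted p = 0.589 with an estimated correlation), and raffinose genes (0.40, 0.0645) passed with the slide block (0.0491, and adjusted p = 0.840 with an estimated correlation).

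Without added ABA, few genes were called for DEX in ABI3:GR, the line that carries the fusion to the receptor. AT3G13310 rose by 2.41 ± 0.22 (adjusted p = 0.00789), AT5G02230, of the HAD hydrolase family, by 2.19 ± 0.16 (adjusted p = 0.00230), AT1G63840, a RING finger gene, by 1.24 ± 0.15 (adjusted p = 0.0470) and AT1G48190 at least 1.41-fold (adjusted p = 0.0209). CHX27, a cation exchanger gene, fell at least 1.47-fold (adjusted p = 0.0380). None of the seed genes was called: EM6 stood at 0.58 ± 0.42 (adjusted p = 0.837), EM1 at least 2.78-fold higher (0.837), ABI5 at 0.10 ± 0.38 (0.960) and RD29B at -2.13 ± 1.26 (0.837). These are 4 rises and 1 fall in limma (9 and 0 with normexp). With the replicate block 12 genes were called, 15 with the slide block and 0 in a model of the 4 arrays alone, where the 16-array model had 1286 at unadjusted p under 0.05. The count was 2 without ABI3:GR mock replicate 1, 9 (6 higher, 3 lower) without ABI3:GR DEX replicate 1, 11 (10 higher, 1 lower) without wild type DEX replicate 2 and 32 (12 higher, 20 lower) without ABI3:GR mock replicate 2. AT3G13310 lost its call without ABI3:GR DEX replicate 2 (adjusted p = 0.0578), AT1G48190 without mock replicate 1 (0.157) or DEX replicate 2 (0.107), CHX27 without mock replicate 1 or DEX replicate 1 (0.254 and 0.132), and AT1G63840 without any single array of the 4 (0.0561 to 0.254). AT1G48190 and CHX27 also lost it with normexp (log2 0.39 and -0.37) and with trend and robust (adjusted p = 0.241 each). AT1G48190 lost it with quantile normalization (0.102), in the value table (0.0948) and with the mean of all probes (log2 0.83), CHX27 with no filter (0.0761), and AT1G63840 with no filter (0.0999) and the mean of all probes (0.0585).

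All 13 tested root markers lay below 0 in DEX-treated ABI3:GR (median -0.93; adjusted p = 5.48e-07, and adjusted p = 0.578 with an estimated correlation; 4 called when adjusted over the list alone). So did all 8 type-A response regulators (median -0.61; adjusted p = 1.95e-05, and adjusted p = 0.628 with an estimated correlation; 1 when adjusted over the list alone). The mock-treated ABI3:GR arrays of this comparison had root markers 0.85 above mock-treated wild type (0.75 with bounds), and under DEX the median difference of the genotypes was -0.342. The LEA list lay higher (median 0.69, 0.51 with bounds; adjusted p = 3.70e-05, and adjusted p = 0.934 with an estimated correlation; 0 when adjusted over the list alone in limma, 3 at unadjusted p under 0.05). That call was lost without ABI3:GR mock replicate 2 (adjusted p = 0.101), without DEX replicate 1 (0.318) and with probes above background on all arrays (0.272). Heat shock genes lay slightly higher (median 0.21, 0.08 with bounds; adjusted p = 0.0299, and adjusted p = 0.934 with an estimated correlation; 1 when adjusted over the list alone). That call was lost without mock replicate 1 (adjusted p = 0.410), without DEX replicate 2 (0.277) and with the mean of all probes (0.167). The storage list had a median of 0.11 (0.00 with bounds; camera adjusted p = 0.115), and passed without wild type DEX replicate 2 (0.0377, and adjusted p = 0.925 with an estimated correlation).

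In ABA-treated ABI3:GR, adding DEX lowered SWEET7, a sugar transporter, at least 12.1-fold (adjusted p = 0.00341). NRT2.3, a nitrate transporter, fell at least 1.43-fold (adjusted p = 0.0421) and WSD1, a wax ester synthase, fell by 1.46 ± 0.18 (adjusted p = 0.0436). AT3G13310 rose by 1.86 ± 0.22 (adjusted p = 0.0421), AT3G49980 at least 1.66-fold (0.0421) and AT5G65100 at least 2.03-fold (0.0488). These 3 rises and 3 falls are all of limma's calls (6 and 9 after quantile normalization, 6 and 10 in the value table). With the replicate block 11 genes were called, with the slide block 18 (7 higher, 11 lower), and in a model of the 4 arrays alone 0, where the 16-array model had 2280 at unadjusted p under 0.05. The count was 1 without wild type DEX replicate 2, 2 without ABI3:GR ABA replicate 1, 10 without ABI3:GR ABA plus DEX replicate 2, 11 without ABI3:GR ABA plus DEX replicate 1 and 28 (10 higher, 18 lower) without ABI3:GR ABA replicate 2. SWEET7 was not called with the mean of its probes (adjusted p = 0.377).

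Apart from SWEET7, these calls depended on single arrays. Without ABI3:GR ABA replicate 1, ABI3:GR ABA plus DEX replicate 1, ABI3:GR ABA plus DEX replicate 2 and wild type DEX replicate 2, the adjusted p was 0.0693 to 0.213 for AT3G13310, 0.0668 to 0.210 for NRT2.3, 0.0685 to 0.127 for WSD1 and 0.0501 to 0.105 for AT5G65100. AT3G49980 lost it without the same arrays except ABI3:GR ABA plus DEX replicate 1 (0.0629 to 0.185), and AT5G65100 had 0.0531 without ABI3:GR ABA replicate 2 and 0.0593 with the slide block. With normexp NRT2.3, WSD1, AT3G49980 and AT5G65100 stood at -0.51, -1.28, 0.09 and 0.12 (log2), not called, nor were they with trend and robust (0.0701, 0.0701, 0.169 and 0.203). None of the 5 was called with no filter (0.0879 to 0.0958) or the mean of all probes (0.0561 each), NRT2.3 and WSD1 not with quantile normalization (0.0706 and 0.0506), NRT2.3 not in the value table (0.0606), and AT3G13310 and WSD1 not with probes above background on all arrays (0.0520 each).

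As a group, storage and oil body genes lay higher with DEX in ABA-treated ABI3:GR. All 20 tested members were above 0, at a median of 2.72 (2.50 with bounds), with 2.60 in experiment 1 and 2.29 in experiment 2 (adjusted p = 2.96e-08, and adjusted p = 0.599 with an estimated correlation). No member passed limma, over all genes or the list alone, with 5 at unadjusted p under 0.05. The SEs include the wide spread of wild type DEX. SESA1 stood at 4.91 ± 2.19, CRA1 at 3.80 ± 2.39, CRC at 3.75 ± 2.72, SESA3 at least 10.0-fold higher, OLEO1 at 2.44 ± 2.09 and OLEO2 at 1.57 ± 1.26, with limma adjusted p between 0.477 and 0.694. The LEA list had a median of 1.39 (1.39 with bounds; adjusted p = 4.68e-05, and adjusted p = 0.599 with an estimated correlation; 0 when adjusted over the list alone in limma, 3 at unadjusted p under 0.05). That call was lost without ABI3:GR ABA replicate 1 or ABA plus DEX replicate 2 and with probes above background on all arrays (adjusted p 0.156). ABI5 stood at 1.09 ± 0.38 (adjusted p = 0.397) and EM1 at 1.58 ± 0.86 (0.541).

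ABA markers (median -0.33, adjusted p = 0.00254) and PP2C genes (-0.34, 0.0277) lay lower with DEX in ABA-treated ABI3:GR and mitotic genes higher (0.25, 0.00159), each with adjusted p = 0.599 with an estimated correlation. No member of the 3 lists was called by limma, over all genes or adjusted over the list alone, with 6, 4 and 1 at unadjusted p under 0.05. The marker call was lost without ABI3:GR ABA replicate 2 or ABA plus DEX replicate 1 (0.0852 and 0.268), with quantile normalization (0.0850) and in the deposited value table (0.102). The PP2C call was lost without the same arrays (0.138 and 0.259), with the slide block (0.0559), with quantile normalization (0.0549) and in the value table (0.0670). The mitotic call was lost without ABI3:GR ABA replicate 1 (0.491) and ABA plus DEX replicate 1 (0.321). With the replicate block 2 more lists passed, both lower, light harvesting (median -0.21, adjusted p = 0.0650 without and 0.0147 with the block) and heat shock genes (-0.38, 0.0890 and 0.0400), and neither with an estimated correlation (0.626 each). Heat shock genes also passed without wild type DEX replicate 2 (0.0148, and adjusted p = 0.530 with an estimated correlation).

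In ABA-treated wild type, the control for that comparison, DEX raised AT3G13310 by 2.29 ± 0.22 (adjusted p = 0.0127) and AT1G77215 at least 2.40-fold (0.0400). RALFL3, a signalling peptide gene, fell at least 2.29-fold (adjusted p = 0.00945) and AT1G66300 at least 2.14-fold (0.0440). The LEA list lay lower there (median -0.74, -0.73 with bounds; adjusted p = 0.000458, and adjusted p = 0.655 with an estimated correlation), as did ABA markers (-0.33, 5.93e-06), PP2C genes (-0.34, 0.000400) and jasmonate genes (-0.24, 0.000364), these 3 with adjusted p = 0.197 with an estimated correlation. The storage list had a median of -0.22 (0.00 with bounds; camera adjusted p = 0.339). Adjusted over the list alone, 0, 0, 0 and 1 members of these 4 lists were called by limma, with 1, 5, 0 and 3 at unadjusted p under 0.05. The LEA call was lost with probes above background on all arrays (adjusted p = 0.292) and the jasmonate call without wild type ABA replicate 2 (0.0534). In all 2 genes were called higher and 2 lower (2 and 3 after quantile normalization, 1 and 2 in the value table, 1 and 0 with normexp). The count was 0 without wild type ABA replicate 2, 1 without wild type ABA plus DEX replicate 1, 2 without wild type DEX replicate 2, 7 (1 higher, 6 lower) without wild type ABA replicate 1 and 12 (10 higher, 2 lower) without wild type ABA plus DEX replicate 2. The 4 arrays alone gave 0 in limma, where the 16-array model had 1428 at unadjusted p under 0.05.

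Each of these 4 calls was lost without some array. AT3G13310 lost it without either wild type ABA array or ABA plus DEX replicate 1 (adjusted p 0.0514 to 0.0745), and RALFL3 without ABA replicate 2 or ABA plus DEX replicate 1 (0.0587 and 0.0514). AT1G77215 lost it without either ABA array or DEX replicate 2 (0.0748 to 0.157), and AT1G66300 without ABA replicate 2, either ABA plus DEX array or DEX replicate 2 (0.0745 to 0.208). With normexp RALFL3, AT1G77215 and AT1G66300 stood at -0.53, 0.58 and -0.64 (log2), not called, nor were they with trend and robust (0.137, 0.142 and 0.172). AT1G77215 and AT1G66300 were not called with no filter (0.0800 and 0.0868), nor AT1G77215 in the value table (0.0550).

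The test of whether the genotypes differ in their response to DEX without ABA called no gene. The gene with the smallest adjusted p, chosen after its values were seen, was AT5G02230, at 1.76 ± 0.23 (adjusted p = 0.207). EM6 stood at 1.13 ± 0.59 (0.864) and ABI5 at -0.37 ± 0.54 (0.905). Limma gave 0 genes with and without the replicate or slide block, and 1100 at unadjusted p under 0.05. The count was 1 without wild type mock replicate 2, 2 without ABI3:GR DEX replicate 1 and 5 without wild type DEX replicate 1 or ABI3:GR mock replicate 2. Root markers, all 13 below 0, differed as a group (median -1.26, adjusted p = 3.68e-06), as did type-A response regulators (-0.68, 0.00552) and heat shock genes (0.53, 0.00320), each with adjusted p = 0.742 to 0.910 with an estimated correlation. Adjusted over the list alone, 2, 0 and 0 members were called by limma, with 4, 0 and 1 at unadjusted p under 0.05. The difference of root markers between the mock-treated genotypes, 0.85, enters this test with its sign turned. The storage list had a median of -2.61 (adjusted p = 0.00320, and adjusted p = 0.910 with an estimated correlation; 0 when adjusted over the list alone in limma, 1 at unadjusted p under 0.05), with 0.00 in experiment 1 and -6.21 in experiment 2. Only 4 of its 20 tested members were well above background in every group of the test, on at least 1 array, and their median was -0.0855.

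Several list results of this test depended on single arrays. The storage median was 0.34 without wild type DEX replicate 2 (adjusted p = 0.584), and the adjusted p was 0.0734 without ABI3:GR mock replicate 2 and 0.0507 with the slide block. Without wild type DEX replicate 2 LEA genes turned from -0.52 (adjusted p = 0.931) to 1.23 (0.00294), and ABA markers (-0.47, 0.0289) and low oxygen genes (0.24, 0.0362) passed as well, each with adjusted p = 0.628 to 0.656 with an estimated correlation. Heat shock genes lost the call without wild type mock replicate 2, wild type DEX replicate 1 or ABI3:GR mock replicate 1 (0.0611 to 0.419), and type-A response regulators without wild type mock replicate 1, wild type DEX replicate 1, ABI3:GR mock replicate 1 or ABI3:GR DEX replicate 2 (0.0611 to 0.103).

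With ABA, the DEX response of the seed lists differed between genotypes at the preset correlation only. All 20 storage and oil body genes had a larger response in ABI3:GR, at a median difference of 2.89 (3.13 in experiment 1, 2.88 in experiment 2; adjusted p = 2.48e-11; 0 when adjusted over the list alone in limma, 2 at unadjusted p under 0.05), and likewise all 22 LEA genes (2.15; adjusted p = 1.97e-12; 1 when adjusted over the list alone). Both had adjusted p = 0.562 with an estimated correlation. The LEA difference joins a median of 1.39 in ABI3:GR to -0.74 in wild type. Of the storage genes 8 of 20 were well above background on at least 1 array of every group of the test (median 2.77, all 8 above 0), and of the LEA genes 20 of 22 (1.98, all 20 above 0). For the other storage genes the difference rests on levels at background. EM1 (3.30 ± 1.22), ABI5 (1.60 ± 0.54) and EM6 (1.21 ± 0.59) did not pass, each at a limma adjusted p of 0.999 or above. The 3 called genes were RALFL3 (3.63 ± 0.41, adjusted p = 0.0498), SWEET7 (-5.41 ± 0.63, 0.0498) and AT3G48640 (-2.90 ± 0.34, 0.0498). RALFL3 and SWEET7 were above background on 2 of the 8 arrays and AT3G48640 on 1. Their differences rest largely on levels at background, so their sizes are not measured. With normexp they were 0.19, -1.95 and -0.74, and with the mean of all probes SWEET7 stood at -0.75 and AT3G48640 at -0.61, none of them called. They count as 1 higher and 2 lower (1 and 1 after quantile normalization or in the value table, 4 and 0 without wild type ABA replicate 1, 3 and 1 without ABI3:GR ABA plus DEX replicate 1).

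These 3 calls sat at the threshold. SWEET7 and AT3G48640 each lost the call without any single array of the 8 and without wild type DEX replicate 2 (adjusted p from 0.0882 to 0.283 and from 0.0540 to 0.283), and RALFL3 without any of them but ABI3:GR ABA plus DEX replicate 1 (0.0894 to 0.283). With the replicate block SWEET7 had adjusted p = 0.0541, and the slide block gave 6 calls in all. With no filter each had adjusted p = 0.103, none was called with trend and robust, RALFL3 had 0.102 with the mean of all probes, and AT3G48640 had 0.541 with quantile normalization and 0.522 in the deposited value table. The count was 0 without wild type ABA replicate 2, wild type DEX replicate 2, either wild type ABA plus DEX array or either ABI3:GR ABA array and 1 without ABI3:GR ABA plus DEX replicate 2. The 8 arrays alone gave 0 in limma, where the 16-array model had 661 genes at unadjusted p under 0.05. Mitotic genes also differed (0.25; adjusted p = 4.78e-05, and adjusted p = 0.562 with an estimated correlation; 0 when adjusted over the list alone in limma, 0 at unadjusted p under 0.05). That call was lost without ABI3:GR ABA replicate 1 (adjusted p = 0.0984) or ABA plus DEX replicate 1 (0.244). Light harvesting genes had a median of -0.23 (adjusted p = 0.0385, and adjusted p = 0.973 with an estimated correlation; 0 when adjusted over the list alone in limma, 0 at unadjusted p under 0.05), which turned to 0.00500 with quantile normalization (adjusted p = 0.187) and 0.0135 in the deposited value table (0.237). The light harvesting call was lost without wild type ABA replicate 2, wild type DEX replicate 2, wild type ABA plus DEX replicate 1, either ABI3:GR ABA array or either ABI3:GR ABA plus DEX array (0.0543 to 0.951), with normexp (0.0759) and with the mean of all probes (0.902).

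The response to ABA without DEX also differed between genotypes. PCC1 (9.31 ± 1.30, adjusted p = 0.0182) and LURP1 (8.52 ± 1.31, 0.0289), above background on all 8 arrays, and ANK (0.00195) fell with ABA in wild type and responded higher in ABI3:GR. ANK was above background on 5 of the 8 arrays, on neither of mock-treated ABI3:GR, so the size of its difference is not measured. RALFL3 (0.0121), AT5G13230 (0.0241) and AT1G19830 (0.0462) were called lower, with sizes that rest largely on levels at background and are not measured, above background on 2, 2 and 3 of the 8 arrays. In all 54 genes were called higher and 4 lower by limma, 92 genes with the slide block and 24 in a model of the 8 arrays alone. Of the 54, 47 were also called lower in mock-treated ABI3:GR than in mock-treated wild type, and 47 fell with ABA in wild type. The mock arrays are shared, and the mock difference enters this test with its sign turned. Independent lists would give overlaps of 0.225 and 5.56. Arrays simulated with no effect hold too few calls to overlap (at most 0 and 1 genes in 100 sets) and say nothing of what shared arrays give among called genes, so part of both overlaps may come from the shared arrays. The count of calls was 26 without wild type ABA replicate 1, 30 without wild type mock replicate 1, 35 without wild type mock replicate 2 and 36 without wild type ABA replicate 2.

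ANK kept its call without each single array. PCC1 lost it (adjusted p in parentheses) without either wild type mock array, wild type ABA replicate 1, either ABI3:GR mock array or ABI3:GR ABA replicate 1 (0.0587 to 0.0806). LURP1 lost it without either wild type mock array, either wild type ABA array, wild type DEX replicate 2 or either ABI3:GR mock array (0.0624 to 0.139). RALFL3 lost it without wild type mock replicate 1, wild type ABA replicate 1, ABI3:GR mock replicate 2 or ABI3:GR ABA replicate 1 (0.0527 to 0.0705). AT5G13230 lost it without any single array of the 8 (0.0516 to 0.117), and AT1G19830 without any but wild type mock replicate 1 and without wild type DEX replicate 2 (0.0651 to 0.173). With normexp RALFL3, AT5G13230 and AT1G19830 stood at -0.20, -0.02 and 0.11, not called, nor were they with trend and robust (0.228, 0.123 and 0.156). LURP1 and AT1G19830 were not called with no filter (0.0563 and 0.0847), nor AT1G19830 with the mean of all probes (0.0504).

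Seed lists lay higher in ABI3:GR in this test. Storage and oil body genes lay at a median difference of 2.07 (0.91 in experiment 1, 4.29 in experiment 2; adjusted p = 1.08e-05; 0 when adjusted over the list alone in limma, 6 at unadjusted p under 0.05) and LEA genes at 2.05 (0.72 and 3.58; adjusted p = 2.41e-06; 3 when adjusted over the list alone). Both had adjusted p = 0.861 with an estimated correlation. Without ABI3:GR ABA replicate 2 the storage median was 1.01 (adjusted p = 0.0766), and with probes above background on all arrays the LEA median turned to -0.41 over 5 members (adjusted p = 0.515). Of the storage genes 4 of 20 were well above background on at least 1 array of every group of the test, at a median of 1.52, and the other differences rest on levels at background. OLEO2, above background on 2 of the 8 arrays, was not called (adjusted p = 0.456), nor was EM6 (1.49 ± 0.59, 0.821). Jasmonate genes lay lower (-0.49; adjusted p = 3.87e-07, and adjusted p = 0.141 with an estimated correlation; 2 when adjusted over the list alone), and ABA markers (-0.06, adjusted p = 0.965) and PP2C genes (0.08, 0.686) did not pass. Heat shock genes (0.40, adjusted p = 0.0853) passed with the replicate block (0.0391, and adjusted p = 0.932 with an estimated correlation) and without wild type DEX replicate 2 (0.0110, and adjusted p = 0.913).

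Whether the DEX response of ABI3:GR depends on ABA was tested last. SWEET7 (-5.57 ± 0.63, adjusted p = 0.0327, above background on 2 of the 8 arrays), AT3G48640 (-3.13 ± 0.34, 0.0327, on 5 of the 8 arrays) and AT5G02230 (-2.20 ± 0.23, 0.0327, on all 8) responded lower with ABA, the 3 genes called by limma (1 higher and 2 lower after quantile normalization or in the value table). SWEET7 rests largely and AT3G48640 partly on levels at background, with -1.82 and -0.95 under normexp and -1.80 and -2.01 with the mean of all probes, not called. They were not called with trend and robust (0.292 and 0.395) either, nor AT3G48640 with quantile normalization (0.460) or in the value table (0.406), AT5G02230 with the mean of all probes (0.689), or any of the 3 with no filter (0.0654). SWEET7 lost the call without any single array of the 8 or wild type DEX replicate 2 (adjusted p 0.0580 to 0.259) and with the replicate block (0.0854). AT3G48640 and AT5G02230 lost it without the same arrays except ABI3:GR mock replicate 2 and ABA replicate 1 (0.0636 to 0.194 and 0.0705 to 0.109). The count was 0 without wild type DEX replicate 2, ABI3:GR mock replicate 1, ABI3:GR ABA replicate 2 or ABI3:GR DEX replicate 2 and 1 without either ABI3:GR ABA plus DEX array. It was 5 with the slide block and 0 in limma on the 8 arrays alone, where the 16-array model had 1018 genes at unadjusted p under 0.05.

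The storage and oil body list responded higher to DEX in the presence of ABA than without it (2.46; adjusted p = 0.000878, and adjusted p = 0.688 with an estimated correlation), a call lost without ABI3:GR ABA replicate 1 or ABI3:GR ABA plus DEX replicate 2 (0.332 and 0.376). Over the 6 of its 20 members well above background on at least 1 array of every group the median was 1.22. Root markers (0.75, adjusted p = 0.000567), type-A response regulators (0.48, 0.0165) and mitotic genes (0.28, 0.0165) also lay higher, and heat shock genes (-0.75, 0.000567) and ABA markers (-0.36, 7.59e-05) lower, each with adjusted p = 0.656 with an estimated correlation. No member of these 6 lists was called by limma, over all genes or adjusted over the list alone, with 1, 0, 0, 0, 1 and 3 at unadjusted p under 0.05. Calls were lost (adjusted p in parentheses) for root markers without ABI3:GR ABA replicate 2, ABI3:GR DEX replicate 2 or ABI3:GR ABA plus DEX replicate 2 (0.0513 to 0.114). They were lost for response regulators without ABI3:GR mock replicate 1, ABI3:GR ABA replicate 2, ABI3:GR DEX replicate 2 or ABI3:GR ABA plus DEX replicate 1 (0.174 to 0.380) and with no filter (0.0998), for mitotic genes without ABI3:GR mock replicate 2, ABI3:GR ABA replicate 1, ABI3:GR DEX replicate 1 or ABI3:GR ABA plus DEX replicate 1 (0.115 to 0.949) and for markers without ABI3:GR DEX replicate 1 (0.0747).

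Overlap of calls was small in the 16-array model. DEX in ABI3:GR and DEX in ABA-treated ABI3:GR, which share no arrays, had 1 called gene in common, AT3G13310. Independent lists would share 0.000687 (Fisher's exact test, p = 0.00137), but these share 1 variance per gene. AT3G13310 passed the threshold in all 4 comparisons of DEX within a genotype, so it is not particular to the fusion. ABA in wild type and DEX in ABI3:GR had 1 in common, AT5G02230, which rose with ABA by 3.52 ± 0.16 (adjusted p = 2.64e-07), where 0.469 would be expected (p = 1, Fisher's exact test). The first count was 2 with the slide block, 0 with no filter, with probes above background on all arrays, with the mean of all probes or with only the arrays of each comparison, and 0 without wild type DEX replicate 2, ABI3:GR ABA replicate 1, either ABI3:GR DEX array or either ABI3:GR ABA plus DEX array. The second was 2 without ABI3:GR DEX replicate 1, 3 without wild type DEX replicate 2 or ABI3:GR DEX replicate 2 and 11 without ABI3:GR mock replicate 2. Fisher's test of it passed with the replicate block (5 shared, p = 0.0193), the slide block (4, p = 0.0190) and probes above background on all arrays (3, p = 0.0349), and without ABI3:GR mock replicate 2 (p = 1.28e-07), DEX replicate 1 (p = 0.0172) or DEX replicate 2 (p = 0.0250), so whether these calls overlap beyond chance stays open.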

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

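The tests of explanations in this part, and the overlap with the mock difference, were chosen only after the result was seen, except that of the mock-treated wild type alone, and the tests of differences between groups were planned. By limma's test of the difference between genotypes, 58 genes differed in their response to ABA, 54 of them higher, of which 47 were also called lower in mock-treated ABI3:GR, a difference on shared arrays that this test contains with its sign turned. By the same kind of test 3 genes differed between genotypes in the DEX response under ABA, and for 3 genes that of ABI3:GR differed with ABA. The test used for a single outlying array needs at least 4 arrays in a group and was not run on these groups of 2.

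RALFL3 had a difference of 3.63 (log2) between genotypes in the DEX response under ABA, and was well above background on the 2 arrays of ABA-treated wild type alone among the 8 arrays of that test. SWEET7 had -5.41 in that test and -5.57 in the test of DEX by ABA within ABI3:GR, and was well above background on the 2 arrays of ABA-treated ABI3:GR alone. AT3G48640 had -2.90 and -3.13 in the same tests, and was well above background on 1 of the 8 arrays of the first and 5 of the second. These sizes rest largely on levels at background, for AT3G48640 in the second test partly, and are not measured differences. None of them passed with normexp. AT5G02230 had -2.20 in the test of DEX by ABA, with a DEX response of 2.19 without ABA.

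The 91 genes called lower in mock-treated ABI3:GR, at a median of -2.42, hold ANK, PCC1 and AT5G03350. A probe mismatch in another strain background, or the slides, would keep the difference under ABA, but among the 59 of these genes well above background on both ABA arrays of wild type the median was 0.182 there, against -1.68 in mock. A state of the mock-treated wild-type plants alone would leave no difference under DEX, but the median there was -1.73 (-1.90 on replicate 1 and -1.61 on replicate 2). An ABA-like state of mock-treated ABI3:GR would raise ABA markers, whose median was 0.0814 in mock (0.41 and -0.02 by replicate) against 4.60 with ABA in wild type. A difference between the lines in these genes that is present without ABA remains a candidate explanation, and growth or plant health of the lines was not tested.

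Storage and LEA genes were higher in ABI3:GR than in wild type under ABA without DEX, for 36 of 42 tested members on replicate 1 and 41 of 42 on replicate 2, and for 27 of the 29 that were well above background in both groups (median 2.20). Set against mock, the 5 LEA members above background on all arrays did not show it (median -0.41, against 0.782 under ABA and 0.449 in mock). A weaker ABA exposure of wild type would raise the difference of ABA markers too, whose median was -0.0598. Seed RNA in the ABI3:GR libraries stays open, since the 5 storage genes that were high on wild type DEX replicate 2 had a median difference of 0.225 (LEA list 2.45) but went both ways, with none of the 5 well above background on the ABA arrays of wild type. Activity of the fusion protein without DEX is a further hypothesis, consistent with a Spearman correlation of 0.314 (Pearson 0.239, covariance 0.651 where shared arrays alone would give -1.16) across the 42 genes, which are not independent replicates, between this difference and the DEX response of ABA-treated ABI3:GR; the value lies just above the 0.3 set for it, and was 0.626 over the 29 genes.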

How the results depend on the processing

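Leaving wild type DEX replicate 2 out of models whose comparison does not hold it was chosen only after seeing the data; all other alternatives were planned. Of 287 alternative counts of calls, 169 stayed within 1.5 times the count reported and 118 did not; the cause was not tested, except that fewer arrays and fewer genes enter some models by construction. The ABA comparisons of both genotypes moved over 1.5 times only with no minimum fold, and the 78 list calls as a count (60 to 89) with no alternative. Of 4792 alternative values of the 305 called values of named genes, 4341 kept direction and call, 449 kept direction without the call and 2 reversed; of 1143 for the 78 list calls, 1041, 96 and 6. Of 4436 for 272 values that were not called, 199 passed. The replicate block ended 2 of 305 gene calls (SWEET7 in genotype by DEX in ABA and in ABA by DEX) and, at the preset correlation, 2 of 78 list calls (expansins in DEX and in ABA plus DEX of wild type), and no others, and added 3 list calls (light harvesting and heat shock for DEX in ABA-treated ABI3:GR, heat shock for genotype by ABA) for 79 in all; the slide block ended 4 and 5, among them expansins in ABA plus DEX of ABI3:GR (adjusted p = 0.0550), and added 5 list calls, the same 3, raffinose for DEX in wild type and light harvesting for ABA in ABI3:GR (0.0470). No minimum fold does not enter camera, camera was not run with trend and robust, and its test of the mock genotypes was not blocked by slide. An array left alone in its group is assumed to vary like the other groups. Probes at background limit the rest: 19510 of 21835 genes were above it on all arrays.

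Calls moved as follows. Quantile normalization gave 15 for DEX in ABA-treated ABI3:GR and 1 for genotype by DEX. The deposited value table gave 16 for DEX in ABA-treated ABI3:GR and 1 for genotype by DEX. Normexp gave 3 for DEX in wild type, 9 for DEX in ABI3:GR, 2 for DEX in ABA-treated ABI3:GR, 1 for DEX in ABA-treated wild type, 0 for genotype by DEX in ABA and 1 for ABA by DEX in ABI3:GR. No filter on dim probes gave 3 for DEX in each genotype, 1 in ABA-treated ABI3:GR and 2 in ABA-treated wild type. It gave 0 for genotype by DEX in ABA, ABA by DEX in ABI3:GR and the overlap of both DEX comparisons of ABI3:GR. Probes above background on all arrays gave 2 for DEX in wild type, 8 for DEX in ABI3:GR, 66 for the genotypes under mock, 0 for DEX in ABA-treated ABI3:GR, 1 for DEX in ABA-treated wild type, 0 for genotype by DEX in ABA, 38 for genotype by ABA, 1 for ABA by DEX in ABI3:GR, 0 for the overlap of both DEX comparisons of ABI3:GR and 3 for the overlap of ABA in wild type with DEX in ABI3:GR. The replicate block gave 12 for DEX in each genotype, 11 in ABA-treated ABI3:GR and 5 for the overlap of ABA in wild type with DEX in ABI3:GR. The slide as a block gave 9 for DEX in wild type, 15 for DEX in ABI3:GR, 18 for DEX in ABA-treated ABI3:GR, 6 for genotype by DEX in ABA, 92 for genotype by ABA, 5 for ABA by DEX in ABI3:GR, 2 for the overlap of both DEX comparisons of ABI3:GR and 4 for the overlap of ABA in wild type with DEX in ABI3:GR. No minimum fold gave 9487 for ABA and 9120 for ABA plus DEX in wild type, and 9826 and 9604 in ABI3:GR. It gave 2 for the overlap of ABA in wild type with DEX in ABI3:GR. Only the arrays of a comparison gave 4 for the genotypes under mock and 24 for genotype by ABA. They gave 0 for all DEX comparisons within a genotype, genotype by DEX in ABA, ABA by DEX in ABI3:GR and both overlaps of calls. Trend and robust gave the counts listed for normexp and 3 for the overlap of ABA in wild type with DEX in ABI3:GR. The mean of all probes gave 11 for DEX in wild type and 3 in ABI3:GR. It gave 0 for DEX in ABA-treated ABI3:GR, genotype by DEX in ABA, ABA by DEX in ABI3:GR and the DEX overlap of ABI3:GR. With single arrays left out the counts ran 0 to 18 for DEX in wild type, 2 to 32 for DEX in ABI3:GR, 53 to 106 for the genotypes under mock, 1 to 28 for DEX in ABA-treated ABI3:GR, 0 to 12 for DEX in ABA-treated wild type, 0 to 5 for genotype by DEX, 0 to 4 for genotype by DEX in ABA, 26 to 64 for genotype by ABA, 0 to 3 for ABA by DEX in ABI3:GR, 0 to 1 for the overlap of both DEX comparisons of ABI3:GR and 1 to 11 for the overlap of ABA in wild type with DEX in ABI3:GR.

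Signs, of the median or of camera, reversed in 8 cases, for causes that were not tested. With single arrays left out the median of the LEA list for DEX in wild type ran from -0.24 to 3.05 and that of the storage list for genotype by DEX from -5.78 to 0.34, each reversing without wild type DEX replicate 2, and that of light harvesting genes for genotype by DEX in ABA from -0.39 to -0.04, where camera turned upward without wild type ABA plus DEX replicate 1 (-0.0408). The last was 0.005 with quantile normalization and 0.0135 in the value table. The LEA median for genotype by ABA was -0.41 over the 5 members above background on all arrays (adjusted p = 0.515). With normexp IRT1 stood at 0.0848 for ABA in ABI3:GR and AT1G19830 at 0.11 for genotype by ABA.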

Other observations

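The comparison below with ABA in DEX-treated wild type, and the tests of carry-over and a DEX response, were chosen after the result was seen. Of the 91 genes lower in mock-treated ABI3:GR, 76 fell with ABA in DEX-treated wild type by limma's calls and 0 rose, against 1750 of all tested genes (8.02%) that fell, where 7.29 would be expected of independent lists (Fisher's exact test across genes, two-sided, p = 1.82e-68). These arrays are not part of the mock comparison. PCC1 went from 3.33 ± 0.01 (log2 level ± SD, n = 2) in DEX-treated wild type to -5.25 ± 1.94 with both treatments, and stood between -5.35 and -4.17 in the 4 groups of ABI3:GR.

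On wild type DEX replicate 2 the storage list lay 7.09 (median, log2) above the mock array of the same number, and on replicate 1 -0.0549, so a response to DEX in both experiments is argued against. Carry-over from another library of the series is argued against by 6 of 22 storage list members that lay more than 1 above every other array. RNA of developing seeds in that library may be the source: 4 of 6 embryo genes lay above each of the 7 other wild-type arrays (ATS3 by 2.80, FAE1 by 2.06, PEI1 by 1.95 and SUS2 by 0.12), while SCPL19 (-0.60) and AT2G25890 (-1.93) did not. The margin of SUS2 is thin, 0 of 3 seed coat and endosperm genes did, and 9.38% of all tested genes were highest on that array among the wild type. A state of those plants that switches on storage genes was not tested apart from it.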
